A study of Mus musculus with 4 samples.

How the data were processed

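RNA was measured in primary hippocampal neurons from newborn C57BL/6NCrl mice on day 12 in culture. The labels give 2 groups of 2 libraries. The control group received the solvent DMSO and kept its basal synaptic activity. The other group received 50 µM bicuculline for 4 h, a blocker of GABA-A receptors that removes synaptic inhibition and sets off bursts of action potentials (AP bursting). The series text names 2 independent experiments on separate cell preparations, so no p-value here speaks for more than 2 preparations. The fit with a replicate block, described below, removes the difference between pairs of libraries. Its p-values rest on a variance trend across genes and not on the spread between preparations. Per the labels' protocols, total RNA was treated with DNase and made into Illumina libraries that do not keep strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart.

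Per the submitters' processing notes, the tools were TopHat 1.2.0, SAMtools 0.1.19 and DESeq 1.12.0, and the genome build was mm9. The annotation and the counting tool are not given in the sources used here. The authors deposited 1 table of 23453 Ensembl genes. Per the file headers, it holds for each gene the normalized signal of each group as the mean of its libraries, the ratio (fold) of AP bursting over control, and a p-value adjusted for multiple testing by the authors. The deposited fold was recomputed from the deposited means and differed by at most 9.93e-09. Log2 folds were computed from the deposited fold. Every per-sample column present was used (0 were left out), because the values come as group means.

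The edgeR test planned before the data were examined needs read counts per library, which the authors did not deposit in their table. The plan's choice for a table of comparisons was followed: the authors' fold and their adjusted p, with a threshold of 0.05. The edgeR test was not run on the read counts worked out later. The authors' p-values could not be adjusted over a gene list alone, because unadjusted values were not used here.

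After the data were examined, the libraries behind each mean were worked out. A mean of 2 libraries with whole reads is a sum of whole multiples of 2 steps, 1 per library. The steps were fitted from the low values, and each mean was searched for the pair of whole read counts that gives it within 1.05 times the rounding of its 10 printed digits, plus the error of the steps. A single pair was found for 23171 control values (98.8%) and 23338 AP bursting values (99.5%). The other 282 and 115 values fitted several pairs and were left unresolved, all of them at 10014.5 or higher in controls and 11362.2 or higher after AP bursting. Of 2000 values moved by a random amount, 1 control and 0 AP bursting values found a pair. On simulated means the resolved pairs were right in 100% of cases. The size factors implied by the steps differed by at most 0.188% from median-of-ratios factors computed on the resolved reads. The unresolved genes are among the most abundant ones, though some genes as abundant, such as Fos, were resolved. The resolved genes hold 70.2% of the control and 82.7% of the AP bursting signal.

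The resolved libraries carry no replicate number. Each group has 1 deeper and 1 shallower library, named here deep and shallow. Across 13648 genes with a mean of at least 50, the difference between the deep and shallow library of the control group correlated with that of the AP bursting group at r = 0.878, and at r = 0.938 among genes with a mean of at least 3000. These correlations are across genes, which are not independent replicates. The deep libraries were therefore treated as 1 pair and the shallow ones as the other, an inference from the data and not from the labels. Whether a pair is 1 of the 2 preparations is not stated.

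limma 3.58.1 in R 4.3.3 was run with a trend on log2(value + 1) of the resolved libraries for 20226 genes with a mean of at least 1, two-sided with Benjamini-Hochberg adjustment, once with the group alone and once with the pair as a replicate block. Folds on this scale understate the change of low genes. In simulated libraries with a known 4-fold change, the fit with the block called 33 of 33 raised and 29 of 33 lowered genes. At 2-fold it called 11 of 33 and 7 of 34, and at 1.5-fold 1 of 34 and 1 of 33. It made 2 calls among 19847 unchanged genes. The fit without the block called 0 of these simulated genes at any of these sizes. The simulated pairs differed alike in both groups, so the simulation does not test calls where the real pairs disagree. The block leaves 1 residual degree of freedom, and the variance of each gene then comes from limma's trend across genes. In a leave-one-out fit 1 group holds a single library, which is assumed to vary like the other group.

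A total of 27 gene lists, 8 of them cell type markers, were written before the data were examined. Each was tested against all other genes with a mean of at least 1 by limma's cameraPR on the authors' log2 fold, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. Camera with an estimated correlation on the resolved libraries without the block is given beside each list that passed. That correlation was estimated with 2 residual degrees of freedom, so a miss there does not show that a list is unchanged. Members were matched by symbol, current or older. Kcnb2, Hmgcs1, Cldn5 and Slc4a1 were not matched. Some lists share members, so their results are not independent. Npas4 and Nr4a1, for example, are in both the immediate-early and the inhibitor-of-death list. Current names, transcript length and GC content came from GENCODE M21, which matched 20850 identifiers and gave GC content for 90.2% of the genes tested. That annotation is on another build than mm9, so no coordinates are printed.

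Named genes followed a rule set before the data were examined: the 10 largest rises and falls past the threshold with a mean of at least 5 and the same direction in both pairs, leaving out names of predicted genes; of each list, the 3 members with the smallest p, or for a marker list with no passing member the 2 with the highest mean; and Fos, Arc, Bdnf, Npas4, Gapdh and Actb. The direction in pairs was read from the resolved libraries and, for genes not resolved, over every pair of read counts that gives the mean. Some members that the rule names are not reported here. Ties at an adjusted p of 1 were broken by the p of the fit with the block, a choice made after the data were seen. Alternatives were the p threshold, a minimum fold, pseudocounts of 0.1 and 5, filters on low values, limma without the trend or with a robust prior, scaling to total reads or the upper quartile, correction for GC content and length by loess, the opposite pairing, and leaving out each library. Calculations outside limma used python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. Ratios of low genes are given from resolved reads with exact 95% intervals, and a group with 0 reads was set to a floor of 3 reads over the group. Intervals and floors cover counting error only.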

Results

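The study measured RNA in 4 libraries of cultured mouse hippocampal neurons, 2 under basal activity and 2 after 4 h of AP bursting, to find genes regulated by synaptic activity. The resolved genes held 20954659 and 13337809 reads in the deep and shallow control libraries and 25572352 and 13229760 reads in the deep and shallow AP bursting libraries. These totals cover 70.2% of the control and 82.7% of the AP bursting signal, so they do not compare depth between groups. The size factors of the deep libraries were 1.33 in controls and 1.27 after AP bursting. Libraries with the same treatment were less alike than libraries of the same depth. Across 13648 genes with a mean of at least 50, log2 levels correlated at r = 0.962 between both deep libraries and 0.936 between both shallow ones, against 0.906 between the controls and 0.873 between the AP bursting libraries. The effect of AP bursting is therefore given for each pair, deep and shallow, for some genes and lists. Other folds from the fit with the replicate block are averages over both pairs, which can differ.

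AP bursting raised a large set of activity-regulated genes, led by transcription factors of the immediate-early class. In the authors' deposited table Fosb, a partner in the AP-1 factor, rose 252-fold from 82.8 to 20891 normalized reads (adjusted p = 1.75e-23). Npas4, a neuronal activity-dependent transcription factor, rose 212-fold and Fos, the classic marker of neuronal activation, 192-fold in the authors' deposited table (adjusted p = 1.15e-21 for both). Arc, which controls AMPA receptor trafficking at synapses, rose 54.4-fold (adjusted p = 2.39e-15) and Bdnf, a neurotrophin, 8.91-fold (adjusted p = 2e-05) in the authors' deposited table. The reference genes Gapdh and Actb had folds of 1.29 and 1.19 there, with an adjusted p of 1.

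In the resolved libraries Arc (ENSMUSG00000022602) stood at 254 ± 45.4 normalized reads in controls and 13838 ± 683 after AP bursting (SD, n = 2 libraries per group). Fos (ENSMUSG00000021250) stood at 160 ± 14.3 and 30704 ± 15279 (SD, n = 2). Bdnf (ENSMUSG00000048482) stood at 1502 ± 1052 and 13378 ± 9357 (SD, n = 2), a wide spread within each group. Its change was nearly equal in both pairs, with log2 folds of 3.15 in the deep and 3.16 in the shallow pair. The log2 folds of Fosb were 6.89 and 9.40 in the deep and shallow pair, those of Fos 6.86 and 8.10, and those of Arc 5.64 and 5.90. Npas4 was too abundant for its libraries to be resolved.

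Of 23453 genes, 143 rose and 0 fell at the threshold in the authors' deposited table, whose processing notes name DESeq. The median fold of these 143 genes was 7.88 and the smallest 4.00, and 23147 genes (98.7%) had an adjusted p of 1. The smallest adjusted p of a lower gene was 0.159, for Inhbb, a subunit of activin and inhibin. Of the 143 genes, 138 could be resolved into libraries; all 138 were higher in both pairs, 136 of them by at least 2-fold in each. limma without a block called 2 genes higher and 0 lower, with 668 genes at an unadjusted p below 0.05. Of 20226 genes tested, limma with the replicate block called 1390 higher and 1234 lower, with 4696 at an unadjusted p below 0.05. All 138 resolved genes that the authors called were among those higher. With scaling to total resolved reads, which moved the median log2 fold of all genes to -0.16, the block split became 991 higher and 1904 lower. Without the trend, limma with the block called 0 genes in either direction and had 3268 at an unadjusted p below 0.05. Leave-one-out fits without the block called 6 genes higher without the control_deep library, 2 without control_shallow, 28 without burst_deep and 12 without burst_shallow, and 0 lower in each.

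**Figure D1:**
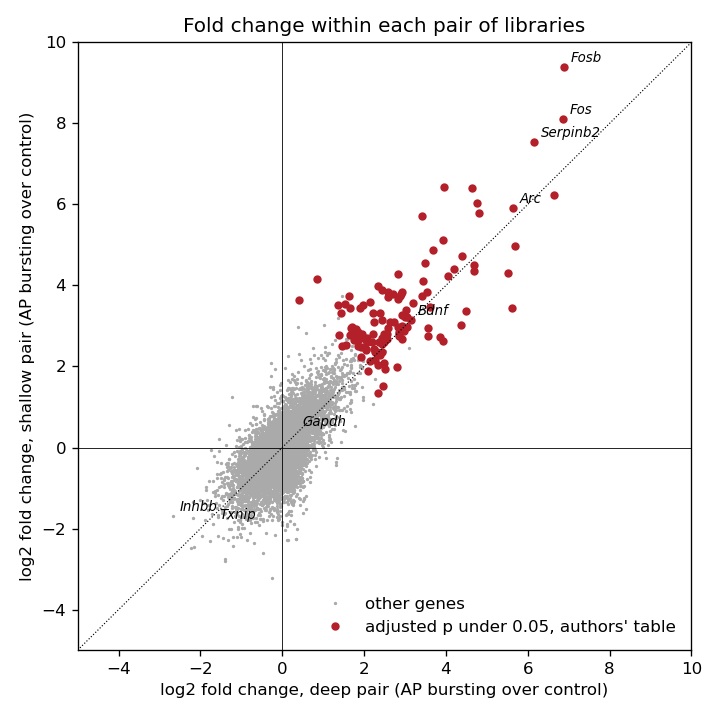
Log2 fold of AP bursting over control in the deep pair (horizontal axis) against the shallow pair (vertical axis), 1 point per gene for 13648 genes with a mean of at least 50. The 123 plotted genes called by the authors all lie above 0 on both axes.

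The 10 largest rises under the naming rule held the 4 activity-regulated genes Fosb, Npas4, Fos and Serpinb2 and 6 genes nearly silent in controls. Serpinb2, a serine protease inhibitor, rose 109-fold from 5.04 to 550 normalized reads in the authors' deposited table (adjusted p = 2.13e-14). Sp7, a transcription factor of bone formation, rose 233-fold there (adjusted p = 3.88e-09), but its controls held 1 read in all against 126 and 103 reads after AP bursting, a ratio of 267 with an exact 95% interval of 47.4 to 10579. The keratinocyte envelope genes Lce1g and Sprr1a rose 90.4-fold (adjusted p = 7.61e-06) and 55.8-fold (adjusted p = 0.00845) and the actin-binding gene Xirp1 63.7-fold (adjusted p = 0.00033) in the authors' deposited table. Counted in reads, the ratio was 80.4 for Lce1g (exact 95% interval 21.8 to 670), 81.5 for Xirp1 (14.2 to 3265) and 48.9 for Sprr1a (8.31 to 1977). Krt6a, a keratin, had 0 reads in controls and 17 and 10 after AP bursting, at least 10.5-fold higher against a floor of 3 reads over the group, with an adjusted p of 0.017 in the authors' deposited table. H2afb3, a histone H2A variant, had 0 reads in controls and 8 and 57 after AP bursting, at least 25.2-fold higher, with an adjusted p of 5.18e-05 in the authors' deposited table. Its values were identical to those of BX005163.13-2, so reads may be shared between copies and the gene of origin is uncertain.

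**Figure D2:**
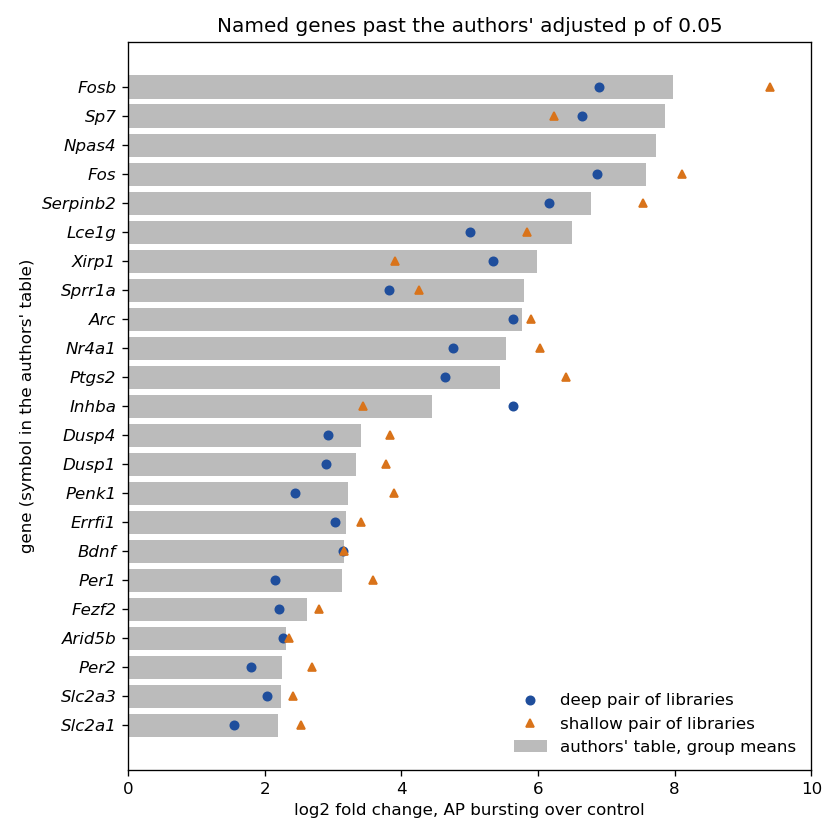
Log2 fold of AP bursting over control (horizontal axis) for 23 named genes past the authors' threshold (vertical axis). Bars give the authors' deposited fold, and circles and triangles give the deep and shallow pair of resolved libraries on the log2(value + 1) scale, both above 0 for each gene that has them; Npas4 has a bar alone.

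Among immediate-early transcription factors, which are switched on without new protein synthesis, 17 of 26 rose and 0 fell in the authors' deposited table. The list stood above other genes by cameraPR (adjusted p = 5.6e-106), and had an adjusted p = 0.212 with an estimated correlation. limma with the replicate block called 21 higher and 1 lower of 23 resolved members, and 21 and 1 adjusted over the list alone. The lower member, Klf10, was looked up after its value was seen and had a log2 fold of -0.97 there. The median log2 fold of the list was 3.42 in the deep and 2.94 in the shallow pair. Nr4a1, an orphan nuclear receptor, rose 46.1-fold in the authors' deposited table (adjusted p = 5.34e-14).

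Of activity-regulated synaptic and secreted effectors, 20 of 30 rose and 0 fell in the authors' deposited table. The set test gave an adjusted p = 2.33e-53 by cameraPR, and an adjusted p = 0.212 with an estimated correlation. Of 30 resolved members limma with the replicate block called 26 higher and 0 lower, with the same numbers adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, rose 43.7-fold (adjusted p = 1.4e-13) and Inhba, the activin A subunit, 21.9-fold (adjusted p = 7.5e-11) in the authors' deposited table. Inhba differed between pairs, with log2 folds of 5.63 in the deep and 3.43 in the shallow pair.

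Of the inhibitor-of-death genes, a group described as giving neurons activity-driven protection, 9 of 10 rose in the authors' deposited table, among them Npas4, Serpinb2 and Nr4a1. The cameraPR test gave an adjusted p = 5.52e-74, and an adjusted p = 0.206 with an estimated correlation. All 9 resolved members were higher in limma with the replicate block, over all genes and adjusted over the list alone (9 higher, 0 lower). Of MAP kinase feedback regulators, 7 of 15 rose in the authors' deposited table. They included the phosphatases Dusp4 (10.7-fold, adjusted p = 5.88e-06) and Dusp1 (10.1-fold, adjusted p = 1.36e-05) and the EGF receptor inhibitor Errfi1 (9.15-fold, adjusted p = 1.7e-05). This list had an adjusted p = 5.77e-19 by cameraPR and an adjusted p = 0.285 with an estimated correlation. limma with the replicate block called 14 of the 15 higher and 0 lower, the same adjusted over the list alone. The median log2 fold was 1.37 in the deep and 2.79 in the shallow pair.

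Of neuropeptides and growth factors, 4 of 34 rose in the authors' deposited table, with Inhba and Bdnf joined by Penk1 (the enkephalin precursor, 9.34-fold, adjusted p = 0.00016). Inhba, Bdnf and Penk1 are also members of the effector list. The neuropeptide and growth factor list passed by cameraPR (adjusted p = 2.06e-08) and had an adjusted p = 0.335 with an estimated correlation. limma with the replicate block called 16 higher and 2 lower of 33 resolved members, and 18 and 2 adjusted over the list alone. The median log2 fold of this list was 0.44 in the deep and 0.94 in the shallow pair. Of clock genes and PAR bZIP factors, 2 of 18 rose in the authors' deposited table, the period genes Per1 (8.73-fold, adjusted p = 9.89e-05) and Per2 (4.75-fold, adjusted p = 0.0251). The cameraPR test gave an adjusted p = 0.0168, and an adjusted p = 0.516 with an estimated correlation. With that block 6 were higher and 0 lower, and 7 and 1 adjusted over the list alone. The median log2 fold of the clock list did not hold its sign across pairs, at -0.09 in the deep and 0.42 in the shallow pair. The clock repressor Cry2 had a fold of 2.83 and an adjusted p of 0.804 in the authors' deposited table.

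Of 25 genes of glycolysis, glucose uptake and lactate transport, 2 rose in the authors' deposited table, both of them glucose transporters and not enzymes of the pathway: Slc2a3 (4.70-fold, adjusted p = 0.0283) and Slc2a1 (4.59-fold, adjusted p = 0.0385). The lactate transporter Slc16a1 had a fold of 3.82 and an adjusted p of 0.0892 there. The list passed by cameraPR (adjusted p = 0.0186) and had an adjusted p = 0.649 with an estimated correlation. With the replicate block 5 of 20 resolved members were higher and 0 lower, the same adjusted over the list alone. The median log2 fold of the list was 0.13 in the deep and 0.31 in the shallow pair. Its libraries also differed within groups, with a median log2 difference of deep minus shallow of -0.48 in controls and -0.71 after AP bursting. Once corrected for GC content and length, these differences were -0.40 and -0.68.

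Genes of energy production in mitochondria gave few calls. In the authors' deposited table, passing genes numbered 0 of 29 for pyruvate dehydrogenase and the TCA cycle (cameraPR adjusted p = 0.700), 0 of 72 for the nuclear-encoded respiratory chain and ATP synthase (0.768), and 0 of 31 for mitochondrial biogenesis, dynamics and calcium uptake (0.304). With the replicate block limma called 1 TCA-list gene higher, Pdk3, a kinase that inhibits pyruvate dehydrogenase (log2 fold 0.90), and 0 lower. It called 0 of 70 resolved respiratory-chain genes in either direction. The median authors' log2 fold of the respiratory chain was 0.02 while its set test pointed down. With the block 4 mitochondrial biogenesis genes were lower and 0 higher, among them Tfam (log2 fold -0.97), Tfb2m (-0.76) and Gabpa (-0.75), which act in transcription of mitochondrial or respiratory genes. In the deep and shallow pair the log2 folds were -0.44 and -1.50 for Tfam, -0.51 and -1.02 for Tfb2m, and -0.61 and -0.89 for Gabpa. Counts adjusted over the list alone were the same for these 3 lists.

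Synaptic receptor and ion channel lists had 0 members past the threshold in the authors' deposited table. Over all 20226 genes tested the block fit called 1390 higher and 1234 lower, so a few calls in a list, here or below, do not set it apart. With the replicate block limma called 2 higher and 1 lower of 26 resolved glutamate receptor and scaffold genes, namely Grin1 (log2 fold 0.50), Dlgap2 (0.59) and Grm7 (-0.57). Of 19 resolved genes of GABA synthesis, transport and receptors, 3 were higher and 0 lower with the block, namely Gad2 (log2 fold 0.56), Slc32a1 (0.57) and Gabrg1 (0.70). In the deep and shallow pair the log2 folds were 0.41 and 0.71 for Gad2, 0.28 and 0.87 for Slc32a1, and 0.22 and 1.18 for Gabrg1. The counts of both lists were the same adjusted over the list alone. Of 45 resolved voltage-gated channel genes, 4 were higher and 5 lower with the block, and 5 and 6 adjusted over the list alone. These included the potassium channel subunits Kcnf1 (log2 fold 1.90), Kcna4 (1.10) and Kcng1 (-1.17). By cameraPR the adjusted p was 0.747 for glutamate receptors, 0.638 for GABA genes and 0.768 for channels. The GABA list missed the threshold in camera with the block (0.125) and passed once GC content was corrected (0.0449). It had an adjusted p = 0.815 in camera with an estimated correlation and the block.

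**Figure D3:**
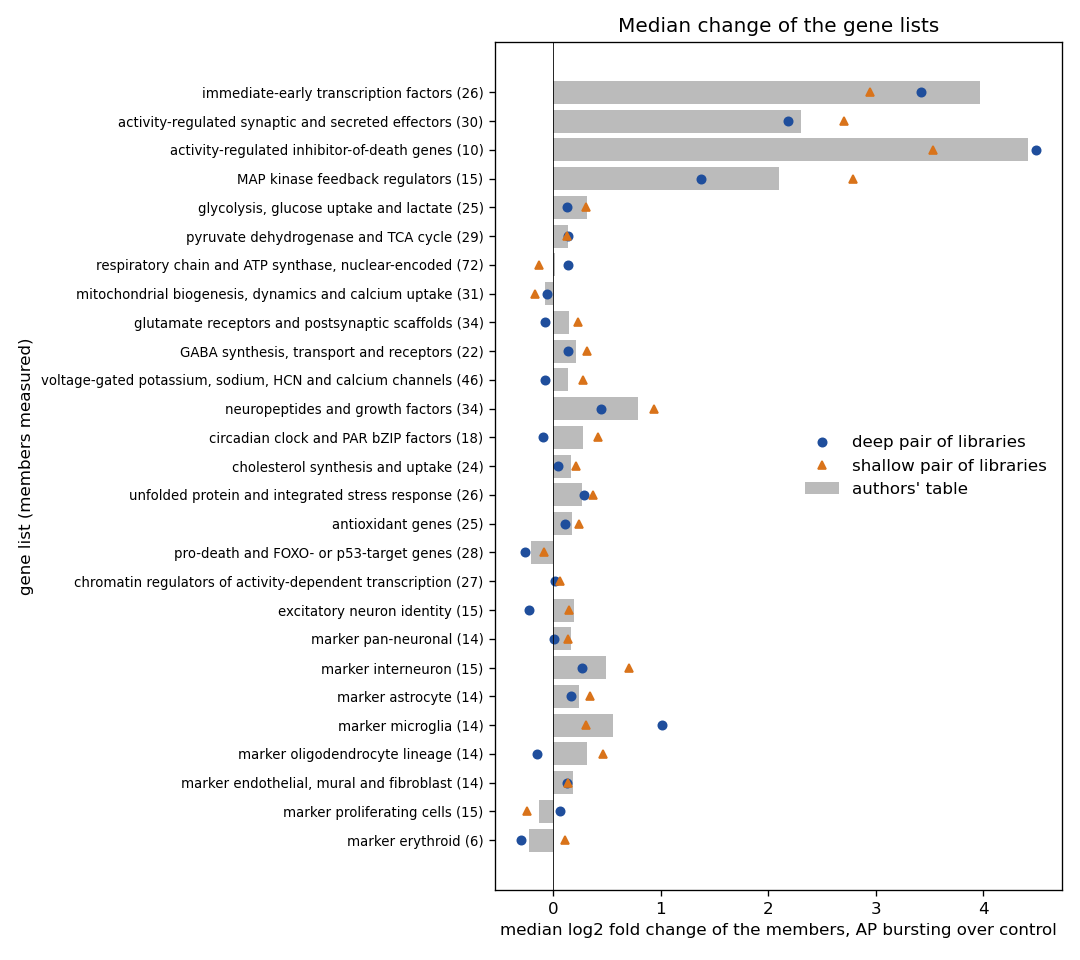
Median log2 fold of AP bursting over control for each gene list. Bars give the median over all measured members in the authors' deposited table, and points give the medians over resolved members in the deep and shallow pair. The inhibitor-of-death list has medians of 4.49 in the deep and 3.53 in the shallow pair, against 0.14 and -0.13 for the respiratory chain.

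The stress-response, antioxidant and cholesterol lists had 0 members past the threshold in the authors' deposited table, and 9 members of the unfolded protein and integrated stress response were higher with the replicate block, of 26 (0 lower; 9 and 0 adjusted over the list alone). With total-read scaling that count was 5. The list had a cameraPR adjusted p of 0.167, and 0.0277 over genes with a mean of at least 50. It passed in camera without the block (0.0492) and with it (0.000484), but had an adjusted p = 0.794 and an adjusted p = 0.809 there with an estimated correlation. Members higher with the block included Sesn2, a stress-induced inhibitor of mTORC1 (log2 fold 1.71), Chac1, which breaks down glutathione, and the stress-response factor Atf4 (1.17). This list also separated the libraries within groups, with a median log2 difference of deep minus shallow of 0.81 in controls and 1.15 after AP bursting once corrected for GC content and length. Among 25 antioxidant genes 3 were higher and 2 lower with the block, the same adjusted over the list alone (cameraPR adjusted p = 0.768). Srxn1, which restores peroxiredoxins, had a log2 fold of 1.60 and Gclc, of glutathione synthesis, 0.98, against -1.80 for the thioredoxin inhibitor Txnip. In cholesterol synthesis and uptake 2 of 23 resolved members were higher and 1 lower with the block, and 4 and 3 adjusted over the list alone (cameraPR adjusted p = 0.700). These were Cyp51 (log2 fold 0.92), Sc5d (0.58) and Dhcr7 (-0.54), all enzymes of sterol synthesis.

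Among 28 pro-death and FOXO- or p53-target genes 0 passed in the authors' deposited table (cameraPR adjusted p = 0.671). With the replicate block 4 were higher and 5 lower, and 5 and 9 adjusted over the list alone. Among them the cell-cycle inhibitor Cdkn1a was higher (log2 fold 1.57), and Bbc3, which encodes the pro-apoptotic PUMA, was lower (-1.16). Of 27 chromatin regulators 1 rose in the authors' deposited table, Arid5b (4.97-fold, adjusted p = 0.0119). With the block 7 were higher and 2 lower, and 8 and 3 adjusted over the list alone, including Tet3, which oxidizes methylated cytosine (log2 fold 1.64), and Arid5a (1.68). The chromatin list had a cameraPR adjusted p of 0.298 and 0.00539 in camera with the block, with a median log2 fold of -0.01 and a mean of 0.27 in that fit. It had an adjusted p = 0.815 with an estimated correlation and the block. Of 15 genes of excitatory neuron identity 1 rose in the authors' deposited table, the deep-layer cortical factor Fezf2 (6.12-fold, adjusted p = 0.00194; cameraPR adjusted p = 0.304). Of 12 resolved members 5 were higher and 2 lower with the block, and 5 and 3 adjusted over the list alone, with Slc17a6, a vesicular glutamate transporter, at a log2 fold of 1.30 and Neurod6, a neuronal differentiation factor, at a fold of 0.493 in the authors' deposited table.

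No cell type marker passed in the authors' deposited table (0 genes in 8 lists). By cameraPR the microglial list stood above other genes (adjusted p = 0.00235) and had an adjusted p = 0.574 with an estimated correlation. It lost the call in camera with the replicate block (adjusted p = 0.0865) and with cameraPR over genes with a mean of at least 5 (0.158), and passed in camera without the block (0.00355) and with cameraPR over genes with a mean of at least 50 (0.00879, 2 members). The median log2 fold of this list was 1.01 in the deep and 0.30 in the shallow pair. Of its 14 members 1 was higher with the block, the lysosomal protein gene Cd68, with a fold of 5.08 and an adjusted p of 0.071 in the authors' deposited table. Of 14 resolved interneuron markers 6 were higher and 0 lower with the block, and 8 and 0 adjusted over the list alone, but 2 with total-read scaling. Their cameraPR adjusted p was 0.167, and 0.0294 over genes with a mean of at least 50. They passed in camera without the block (0.00602) and with it (0.00539), but had an adjusted p = 0.422 and an adjusted p = 0.815 there with an estimated correlation. Gad1 and Reln had folds of 1.40 and 1.46 in the authors' deposited table.

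The other marker lists held 0 or 1 member called with the replicate block, over all genes and adjusted over the list alone. These single members were Sox9 of 14 astrocyte markers (log2 fold 1.03, picked after its value was seen) and Fn1 of 14 endothelial, mural and fibroblast markers (0.60). There were 0 of 5 resolved pan-neuronal, 0 of 14 oligodendrocyte-lineage, 0 of 15 proliferation and 0 of 6 erythroid markers. By cameraPR their adjusted p was 0.671 for pan-neuronal, 0.768 for astrocyte, 0.671 for oligodendrocyte, 0.700 for endothelial, 0.671 for proliferation and 0.700 for erythroid markers. In the authors' deposited table the neuronal microtubule gene Mtap2 had a fold of 1.13, Slc1a3 and Glul of astrocytes 1.29 and 1.18, and Olig1 of the oligodendrocyte lineage 1.28. The folds there were 1.16 for the fibroblast gene Dcn, 0.818 and 0.812 for the proliferation genes Ccna2 and Mcm2, and 1.63 and 1.51 for Hba-a1 and Hba-a2, near-identical globin copies whose reads cannot be assigned with certainty. Non-neuronal markers separated the libraries within both groups: after correction for GC content and length, 67 markers had a median log2 difference of deep minus shallow of -0.62 in controls and -0.70 after AP bursting.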

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

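The libraries were resolved after the data were seen, so every fit on them was chosen then, leave-one-out fits among them; changes of the authors' threshold were planned, as were set tests by fry or with an estimated correlation, both without the block. The libraries carry no replicate number, so the replicate block rests on pairs inferred from the data. Of the 143 genes the authors called, 95 passed at a threshold of 0.01. On the resolved libraries limma called 2 genes higher without the block, 61 without the block but with GC correction, and 1390 with the block. Leave-one-out fits gave 2 to 28. None was lower by the authors' test, and 1234 were with the block. The 1390 higher genes became 702 with at least a 2-fold change, 822 with a minimum fold of 1.2, 37 with the opposite pairing and 0 without the trend. The 1234 lower genes became 718 at a threshold of 0.01, 428, 459, 0 and 0 under those settings, and 1904 with total-read scaling. Over all lists 55 members rose by the authors' test, 2 without the block, 2 to 18 in leave-one-out fits and 134 with the block, and 0 fell against 25 with the block. Of 8 lists past the cameraPR test, 0 passed with an estimated correlation and 0 by fry, with or without the block. These fits had 2 residual degrees of freedom without the block and 1 with it, so the misses do not decide whether the lists changed. The causes of these shifts were not tested, except that the block removes the difference between pairs and a stricter threshold or minimum fold keeps fewer genes by construction. Of 72 named genes with finite folds and resolved libraries, all 22 called by the authors kept their direction in each fit that tested them. That is little evidence of robustness, because these genes were called on the same libraries. All 22 stayed past the threshold with the block, 13 with the opposite pairing, 2 without the block and 0 without the trend, and 34 of the other 50 passed with the block. The planned edgeR test was not run, because the deposited values are group means and not read counts per library. Neither edgeR nor DESeq2 was run on the resolved reads. The authors' p-values were not adjusted over a list alone. No erythroid marker reached a mean of 50, so that set test gave no value. Some of the most abundant genes could not be resolved, and low genes are limited by reads, as for Krt6a with 27 reads in all.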

Other observations

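All tests in this part were chosen after the results were seen, and the genes named were picked from their values. Outside the fixed lists, 88 of the 143 genes that rose in the authors' deposited table remained. They included Pim1, a serine/threonine kinase gene (40.9-fold, adjusted p = 1.75e-12), Cyr61, a secreted matrix protein gene (19.9-fold, adjusted p = 4.43e-08), Trib1, a pseudokinase gene (10.7-fold, adjusted p = 1.12e-05), and Sgk1, a serum- and glucocorticoid-regulated kinase gene (8.75-fold, adjusted p = 2.23e-05). Synaptic and matrix genes among them were Pcdh8, an activity-regulated protocadherin (8.85-fold, adjusted p = 0.000136), Acan, the aggrecan core of perineuronal nets (5.92-fold, adjusted p = 0.00222), and Rgs4, a regulator of G-protein signalling (5.26-fold, adjusted p = 0.0132), all in the authors' deposited table. The neighbouring microRNA entries mmu-mir-132 and mmu-mir-212 rose 31.2-fold and 27.1-fold there (adjusted p = 1.05e-05 and 6.01e-05). Reads of these entries can come from the unspliced host transcript, so mature microRNA levels are not measured.

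Genes that were lower with the replicate block had a median log2 fold of -0.88, and a median fold of 0.564 in the authors' deposited table. Among those with large falls were Dclk3, a doublecortin-like kinase gene (log2 fold -2.35), Inhbb (-2.19), Chst12, a chondroitin sulfotransferase gene (-2.08), and Stat2, a transducer of interferon signals (-1.68). Inhbb was lower while Inhba, which encodes the other activin subunit, rose 21.9-fold in the authors' deposited table. Genes with a Zfp number as symbol, most of which encode zinc-finger proteins, were frequent among the lower genes, a feature noticed among the largest falls and given as counts, since a test on the same falls would restate it. Of 295 such genes, 100 were lower and 16 higher with the block, which is 33.9% lower against 5.69% of other genes. Their median log2 fold was -0.47, and 200 were lower and 39 higher in both pairs. Before correction for GC content and length, they also separated the libraries within groups. The median log2 difference of deep minus shallow was 0.47 in controls and 0.74 after AP bursting, and a part from GC or length bias stays open. With correction for GC content and length 97 were lower and 19 higher of 282, with upper-quartile scaling 94 and 14, and with total-read scaling 127 and 11. Many of these genes are close paralogs, so reads assigned to single members are uncertain. Others rose in the authors' deposited table, such as Zfp516 (6.70-fold, adjusted p = 0.00151) and Zfp184 (5.97-fold, adjusted p = 0.0159).

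The deep and shallow library of a group differed in the same genes in controls and after AP bursting. Sampling noise of reads is argued against by the correlation of these differences, which was 0.938 among genes with a mean of at least 3000. GC content with length as the whole cause is argued against by the correlation of 0.765 left after correction for both. At a mean of at least 50, the SD of the log2 difference was 0.80 in controls and 0.98 after AP bursting. After that correction it was 0.54 and 0.66 over 12674 genes, so a part of the difference went with GC content and length. A lower share of neurons in the shallow libraries may contribute. Non-neuronal markers had a median of -0.62 for deep minus shallow in controls and -0.70 after AP bursting, where random lists of matched expression had -0.01 and -0.03. In both groups 0% of these random lists lay at or below the marker median. Of the 6 lists 12 of 12 medians lay below 0. That count alone is weak, because random lists also lay below 0 for most of them, as for microglia (-0.23 and -0.11). The 5 resolved pan-neuronal markers stood at 0.49 in controls and 0.46 after AP bursting, where random lists of matched expression had medians of 0.19 and 0.13. Of those random lists, 95.9% and 89.3% lay at or below the pan-neuronal median. Not all lists follow this explanation, so it stays open: excitatory identity genes had medians of -0.17 and -0.73. After AP bursting 42.0% of random lists of matched expression lay at or below the microglial median and 50.7% at or below that of interneurons. A biological difference between the deep and shallow pair was not tested.

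With the replicate block 1234 genes were lower, and 0 in the authors' deposited table. An effect of variance shared across genes as the whole cause is argued against only for 616 of them, taken as a set. These had a mean of at least 50 and a fall of at least 1.5-fold in both pairs. Of all genes at that level 665 fell this far in both, and 171 would if pairs were independent. Single genes are therefore not cleared. The 13 genes that changed in opposite directions add little, because pairing libraries by their alike differences keeps such changes few. An effect of shared variance stays open for the 471 other lower genes at that level. There 1381 genes fell by at least 1.2-fold but not 1.5-fold in both pairs, against 511 in opposite directions and 862 for independent pairs. It also stays open for the 147 with a mean under 50. There 524 genes fell by at least 1.5-fold in both pairs and 542 changed in opposite directions. GC content or length bias is argued against by 1138 of 1153 lower genes that stayed past the threshold after correction. Spread between the libraries of a group could account for the absence of the lower genes from the authors' calls. Their standard error in limma without the block was a median 2.12 times that with it. That ratio cannot decide the point, because the fit with the block selected these genes and the authors' own errors were not compared. Repression by AP bursting is a hypothesis that these data leave open, since pairs were inferred from the same libraries.

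Cd68 stood at 49.2 ± 4.61 normalized reads in controls and 250 ± 4.77 after AP bursting (SD, n = 2), with log2 folds of 2.25 and 2.40 in the deep and shallow pair. More microglia in treated cultures as the whole cause are argued against by the other 13 microglial markers, whose median log2 fold in the authors' deposited table was 0.38 and upper quartile 0.78, below the lower bound of 1.79 for Cd68 in limma with the replicate block, and by Csf1r, at 42.8 in controls and 45.4 after AP bursting. A smaller increase stays open, because 8 of these 13 were higher and 1 lower in both pairs and most had few reads, among them Cx3cr1 and P2ry12, the 2 above that bound, which went from 0.547 to 3.51 and from 1.09 to 5.03 normalized reads. A fixed share of reads from Eif4a1, the gene next to it, is argued against by its log2 fold of 0.30. Transcription of Cd68 in neurons, activation of the microglia present or transcripts of Eif4a1 that run into Cd68 may account for the change, and none of these was tested.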
